A study of Homo sapiens with 2 samples.

How the data were processed

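Small RNA was sequenced from 2 human small cell lung cancer cell lines, H446 and SHP77, with 1 library per line. Per the labels, H446 was derived from a pleural effusion metastasis and is chemosensitive, SHP77 was derived from a primary lung tumor and is chemoresistant, and both were untreated. Per the labels' protocols, cells grew in 1640 medium with 10% fetal bovine serum, total RNA was ligated to 3' and 5' adapters, amplified, size selected on a gel with the NEBNext small RNA kit and sequenced as 50-base single-end reads on a HiSeq 2500. The labels give the molecule as polyA RNA, which differs from the small RNA ligation in their protocol; the protocol was followed here. The submitters' processing notes name the genome build hg19 and the tools bcl2fastq and BWA, without versions or roles. The miRNA annotation release, the adapter trimming, the allowed mismatches and the treatment of reads matching several miRNAs are not given in the sources used here.

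The deposited files list, per the file headers, a read count for each mature miRNA and an expression value that is in CPM, counts scaled to a common library total. Each value equals the authors' deposited count divided by a library total, with a largest gap of 0.0275 CPM in H446 and 0.0230 CPM in SHP77. The total implied was 8830490 counts for H446 and 1062855 for SHP77, which exceeded the sum of the listed counts by 2151 and 1553 counts, or 0.0244% and 0.146% of each total. The smallest count above 0 in either library was 10, so a listed 0 stands for any count from 0 to 9. That limit was 1.02 CPM in H446 and 8.48 CPM in SHP77, so low miRNAs were measured less well in SHP77.

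CPM values were computed here from the deposited counts and the sum of the listed counts, 8828339 for H446 and 1061302 for SHP77. The ratio is SHP77 over H446 on the log2 scale with no pseudocount. A listed 0 was set to 9 counts, so that the fold is a lower bound, and a miRNA was left without a ratio where that bound gave no direction. A floor of 3 counts had been planned, and it was replaced after the files showed no count from 1 to 9. The count of differing miRNAs took those at 10 CPM or more in at least 1 library and a size of at least 4-fold. With 1 library per line there is no replicate error, so no p-value was computed across miRNAs, and the fixed rule of size takes the place of a test. The 95% intervals are exact Poisson intervals for levels, Wilson intervals for shares, exact conditional binomial intervals for ratios of 2 counts, and intervals from counting error for arm ratios. Reads carry no molecular identifiers, so all intervals and floors cover counting error only.

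Before the data were examined, the comparisons, the alternatives, 22 lists of miRNAs and the rule for naming miRNAs were fixed. The rule names the 10 most abundant miRNAs of each library, the 12 largest ratios in each direction among miRNAs at 100 CPM or more in a library, up to 4 most abundant members of each list, and the 5 hairpins with the largest difference in arm ratio. It named 85 miRNAs and these hairpins; other miRNAs given by name in the text were chosen after their values were seen. The lists were the let-7 family, the miR-17-92 cluster with its paralogs, neuronal and neuroendocrine miRNAs, the miR-200 family with other epithelial miRNAs, mesenchymal-enriched miRNAs, the miR-34 and miR-449 family, the DLK1-DIO3 imprinted cluster, the chromosome 19 cluster, the miR-302 with miR-371-373 clusters, the miR-506-514 cluster, HOX cluster miRNAs, the miR-183-96-182 cluster, the miR-15 with miR-16, miR-23-27-24, miR-29, miR-30 and miR-181 groups, miRNAs linked to drug response, and markers of blood cells, endothelium, muscle and liver. For each list with at least 3 members compared, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The random lists drew miRNAs without regard to shared hairpins or clusters. Neighbouring hairpins often had similar ratios, so the percentiles can overstate how unusual a list of neighbours is. Arm ratios were taken for hairpins with at least 50 counts over both arms in each library.

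Names were matched to hairpin genes of GENCODE 29, which is on GRCh38, for 755 of the 770 miRNAs above 0. As the submitters' build is hg19, only chromosomes, host genes and neighbours within 10 kb were used, and no coordinates are given. GC content is that of the side of the annotated hairpin that holds the arm, split at its middle. Names of 1 family with equal counts in both libraries were sought only above a minimum count. Some names at 10 CPM or more in a library fell under that minimum and were not searched. Those found formed 5 sets of 11 names, including miR-365a-3p with miR-365b-3p and miR-199a-3p with miR-199b-3p. Their reads cannot be assigned to a single gene. Members of families with near-identical sequences, such as let-7, may share reads as well.

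Alternatives were median-of-ratios size factors, TMM factors, the total without the 10 most abundant miRNAs, 1 CPM added to both libraries, other minimum levels, a size of at least 2-fold, at least 200 counts per hairpin and 1 count added to each arm. Chosen after seeing the data were the authors' totals, equal names taken once, miRNAs above 0 in both libraries, thinning of H446 to the SHP77 total in 100 draws, the same with size factors, and removal of a GC trend by lowess with a span of 0.5. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3. The steps were tested on counts simulated for SHP77 over H446 across 455 miRNAs: 95.7% of the intervals held the true ratio, and the rule of 4-fold called 100% of miRNAs raised 8-fold, 80.0% of those lowered 8-fold, 2.00% of those changed 2-fold and 0% of the unchanged. The simulated counts varied by Poisson counting error only. These rates check the computation and do not cover variation between libraries of a line.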

Results

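Mature miRNAs were counted in 1 small RNA library of H446, a chemosensitive small cell lung cancer line, and 1 of SHP77, a chemoresistant line of the same cancer. The design compares the miRNA content of the chemosensitive line with that of the chemoresistant one. With 1 line of each kind, drug response cannot be told apart from the origin of the line (metastasis or primary tumor) or from other differences between the lines. The listed counts summed to 8828339 in H446 and 1061302 in SHP77, so H446 was the more deeply sequenced library. Of 2656 miRNA names, 682 were above 0 in H446 and 450 in SHP77. Both libraries held 362 of them, 320 were above 0 in H446 only and 88 in SHP77 only. There are no replicates, so each difference is between these libraries, and no replicate spread is available to set it against.

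The most abundant miRNA was let-7a-5p, of a family that represses RAS and MYC, in H446 and miR-7-5p, a miRNA enriched in neurons and endocrine cells, in SHP77. let-7a-5p took 13.3% of H446 counts (95% Wilson interval 13.273 to 13.318%) and 5.79% of SHP77 counts. miR-7-5p took 20.8% of SHP77 counts (95% Wilson interval 20.714 to 20.868%) and was at 11269 CPM in H446, where it ranked 20. miR-21-5p, a miRNA abundant in many tumors, was at 97449 CPM in H446 and 81639 CPM in SHP77. miR-148a-3p, miR-375-3p and miR-30d-5p were in the top 10 of SHP77 besides miR-7-5p, whereas miR-100-5p, miR-99a-5p, miR-30c-5p and miR-24-3p were in that of H446. The other 6 of each top 10, let-7a-5p, let-7f-5p, let-7i-5p, miR-21-5p, miR-92a-3p and miR-26a-5p, were shared. The 10 most abundant miRNAs held 60.8% of the counts in H446 and 66.4% in SHP77. Across the 354 miRNAs above 0 in both libraries and at 10 CPM or more in 1 of them, the levels had a Pearson correlation of 0.70 on the log2 scale and a Spearman correlation of 0.64; these are across miRNAs, which are not independent replicates.

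**Figure D1:**
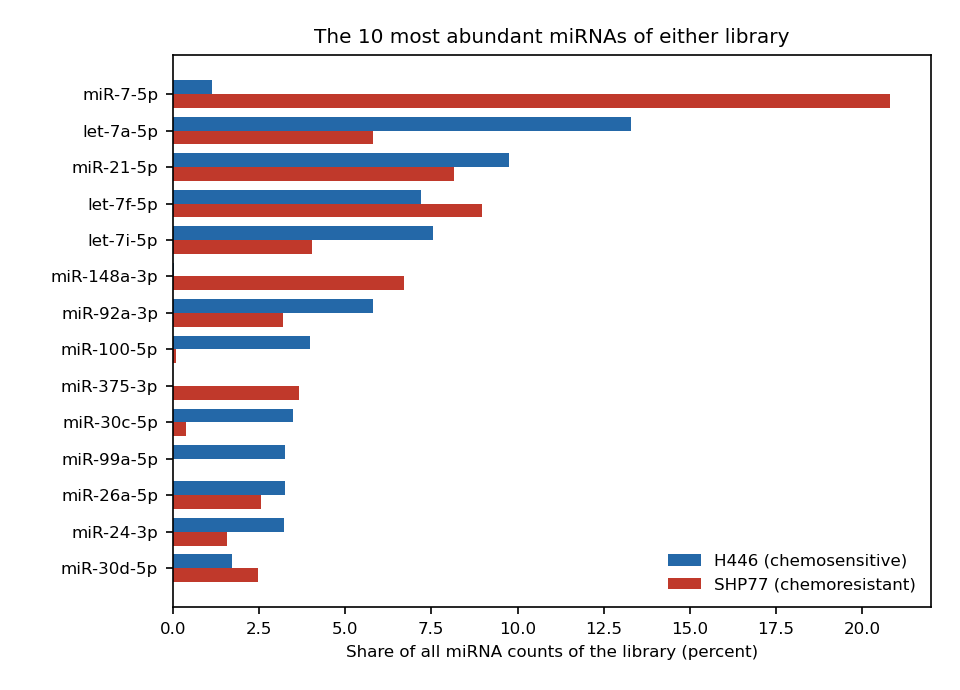
Share of all miRNA counts, in percent, of the miRNAs in the top 10 of either library, with H446 in blue and SHP77 in red (1 library each). miR-7-5p reached 20.8% in SHP77, and let-7a-5p reached 13.3% in H446.

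SHP77 held high levels of miRNAs of neuroendocrine and neural cells that were low or at 0 in H446, and H446 held high levels of miR-224-5p, miR-99a-5p, miR-100-5p and both arms of miR-30a that were at least 44.1-fold lower in SHP77. miR-375-3p, a miRNA of neuroendocrine and pancreatic islet cells, was at 36646 CPM in SHP77 and listed at 0 in H446, at least 35948-fold higher. miR-9-5p, abundant in brain, had 375 counts in H446 and 22768 in SHP77, 505-fold higher (95% interval 456 to 561). miR-224-5p and miR-452-5p, which lie within the GABRE gene on chromosome X in GENCODE 29, were at 11335 and 1625 CPM in H446 and listed at 0 in SHP77, at least 1337-fold and 192-fold lower. miR-99a-5p, on chromosome 21, had 288516 counts in H446 and 110 in SHP77, 315-fold lower (95% interval 262 to 384).

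Among the 12 largest ratios toward SHP77, miR-9-3p, miR-135a-5p, miR-3960, miR-1269a, miR-1269b and the miR-3689 names were listed at 0 in H446. miR-9-3p was at least 987-fold higher and miR-135a-5p at least 560-fold higher. miR-3960 was at least 296-fold, miR-1269a at least 241-fold and miR-1269b at least 230-fold higher. The names miR-3689a-5p, miR-3689b-5p and miR-3689e had the same 279 counts in SHP77 and were at least 258-fold higher, and their reads cannot be told apart. miR-381-3p was 292-fold higher (95% interval 212 to 415) and miR-7704 was 241-fold higher (95% interval 182 to 325). miR-148a-3p, which the rule named for its abundance, was 176-fold higher (95% interval 170 to 182), and miR-7-5p was 18.4-fold higher (95% interval 18.3 to 18.6).

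Among the 12 largest ratios toward H446, miR-30a-3p was 210-fold lower in SHP77 (95% interval 133 to 354) and miR-30a-5p was 128-fold lower (95% interval 107 to 153). miR-31-5p was at least 199.9-fold lower and miR-155-5p, processed from the transcript MIR155HG, at least 109.7-fold lower. miR-365a-3p and miR-365b-3p, whose reads were counted alike, were 62.2-fold lower (95% interval 46.6 to 84.9). miR-30c-2-3p and miR-125b-2-3p were listed at 0 in SHP77 and were at least 47.6-fold and 45.9-fold lower. miR-100-5p was 44.1-fold lower (95% interval 41.4 to 47.1).

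**Figure D2:**
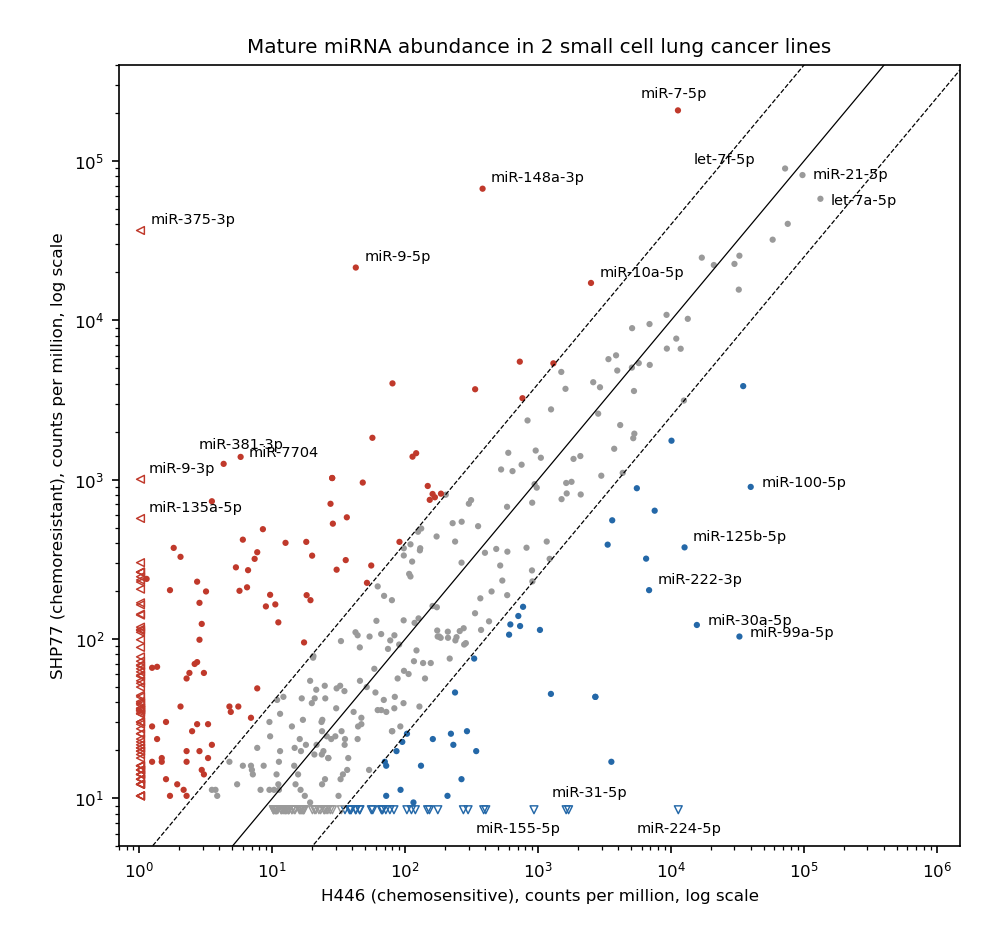
CPM of each miRNA at 10 CPM or more in a library, in H446 (horizontal axis) and SHP77 (vertical axis), both on log scales. The solid line marks equal levels and the dashed lines 4-fold differences; red points were at least 4-fold higher and blue points at least 4-fold lower in SHP77, and open triangles are miRNAs listed at 0 in a library, drawn at the level of 9 counts (1.02 CPM in H446, 8.48 CPM in SHP77).

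Of 511 miRNAs at 10 CPM or more in a library, 247 differed by at least 4-fold, 177 higher and 70 lower in SHP77. The higher ones made up 71.7% of these, and 61.3% with 1 CPM added to both libraries, where 174 were higher and 110 lower. Depth bears on this split, since a listed 0 allowed up to 8.48 CPM in SHP77 and up to 1.02 CPM in H446. With H446 thinned to the SHP77 total, 117 were at least 4-fold higher and 69 lower. Scaling bears on all ratios: the median log2 ratio of 354 miRNAs was 0.35, median-of-ratios factors shifted every ratio by -0.37, TMM factors by -0.42, and the total without the 10 most abundant miRNAs by 0.35.

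Neuronal and neuroendocrine miRNAs were higher in SHP77. Of 21 members compared, 12 were at least 4-fold higher, 1 was at least 4-fold lower and 8 lay between. The median log2 ratio was 3.59, above 99.94% of the random lists, and 1.67 over the 12 members above 0 in both libraries, which leaves out those listed at 0 in either. The list summed to 2.02% of counts in H446 and 27.9% in SHP77, most of it miR-7-5p. miR-129-5p was at 47.9 CPM in H446 and 959 CPM in SHP77 and miR-218-5p at 113 and 1395 CPM, while miR-128-3p had a log2 ratio of -0.40 and miR-138-5p was listed at 0 in SHP77 against 57.0 CPM in H446. Depth bears on the counts of higher and lower members. miR-124-5p, miR-129-2-3p and miR-95-5p, listed at 0 in H446, had only 15, 11 and 13 counts in SHP77 and passed 4-fold by the low floor of H446. In the other direction miR-219a-1-3p, at 90 counts in H446 and 0 in SHP77, had a log2 bound of only -0.27. The miR-183-96-182 cluster, expressed in sensory and neuroendocrine cells, had 4 of 5 members at least 4-fold higher and a median of 2.92, within the random range of -2.64 to 3.60. miR-183-5p was 7.56-fold higher and miR-96-5p 12.1-fold higher. miR-182-5p had a log2 ratio of 2.04, which became 1.67 with median-of-ratios and 1.63 with TMM factors, leaving 3 of 5 members at least 4-fold higher. With the total without the 10 most abundant miRNAs all 5 were.

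The imprinted DLK1-DIO3 cluster on chromosome 14, whose miRNAs are expressed from the maternal allele, was higher in SHP77. All 38 members compared were at least 4-fold higher, and their median log2 ratio of 4.89 was above all random lists (95% of which lay between -0.29 and 3.69). A member at 0 in H446 and at 10 CPM or more in SHP77 was called higher by rule, since that 0 stood for at most 1.02 CPM. Over the 15 members above 0 in both libraries the median was 5.15, and the lowest log2 ratio was 3.15 (miR-493-5p). The members are neighbours and not independent, so the place among random lists overstates how unusual the list is. The sum over the cluster was 63.8 CPM in H446 and 4921 CPM in SHP77. miR-370-3p was 208-fold higher (95% interval 146 to 309), miR-379-5p 206-fold higher (95% interval 125 to 364) and miR-127-3p 16.7-fold higher (95% interval 13.9 to 20.2). Of its 92 names, 39 were above 0 in SHP77 and 15 in H446, where miR-127-3p was the most abundant at 19.9 CPM.

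Epithelial and mesenchymal lists differed in opposite directions by their medians, but the mesenchymal list was split. Members of the miR-200 family repress ZEB1 and ZEB2. Of 6 members compared of that family and other epithelial miRNAs, 4 were at least 4-fold higher in SHP77, 1 was at least 4-fold lower and 1 lay between, with a median log2 ratio of 5.92, above 99.6% of the random lists. The 4 higher members, miR-200a-3p, miR-200a-5p, miR-200b-3p and miR-429, come from 1 cluster on chromosome 1. They are not independent, so the percentile overstates how unusual the list is. miR-200a-3p rested on 10 counts in H446 and 253 in SHP77, 210-fold higher (95% interval 113 to 444), miR-200b-3p was 57.6-fold higher, miR-429 at least 75.8-fold higher and miR-200c-3p 3.59-fold higher, while miR-203a-3p was listed at 0 in SHP77 against 76.7 CPM in H446. Of 20 mesenchymal-enriched members, 7 were at least 4-fold higher, 11 at least 4-fold lower and 2 lay between. Their median was -3.26, below all random lists, but it was 4.21 over the 11 members above 0 in both libraries, a restriction that leaves out lower members such as miR-31-5p and miR-155-5p because they were listed at 0 in SHP77. miR-199a-3p and miR-199b-3p had equal counts; with such names taken once, a choice made after the values were seen, 6 of 19 members were at least 4-fold higher and 11 lower, and the median was -4.34. It was then -0.07 over the 10 members above 0 in both libraries. Over the 14 members of the full list at 100 CPM or more it was -5.04, and the list summed to 10.2% of counts in H446 and 0.516% in SHP77, 19.8-fold lower. Lower in SHP77 were miR-125b-5p, at 12635 against 376 CPM, and miR-221-3p and miR-222-3p, which target the cell cycle inhibitor CDKN1B, at 6491 against 319 CPM and 6835 against 203 CPM. Higher in SHP77 were miR-143-3p and miR-145-5p, abundant in smooth muscle, with log2 ratios of 4.69 and 5.73, and the miR-199a and miR-199b arms, with log2 ratios from 4.21 to 5.51.

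The let-7 family was lower in SHP77 by its median. Of 19 members, 6 were at least 4-fold lower, 1 was at least 4-fold higher and 12 lay between, with a median log2 ratio of -1.20, above 0.400% of the random lists. Members at least 4-fold lower numbered 9 with median-of-ratios or TMM factors and 3 with the total without the 10 most abundant miRNAs. The family summed to 34.1% of counts in H446 and 22.3% in SHP77. let-7c-5p had a log2 ratio of -2.64 and let-7i-5p of -0.90, whereas let-7f-5p had 0.32, which turned to -0.06 with median-of-ratios factors, and miR-98-5p had 1.21. The miR-17-92 cluster with its paralogs, activated by MYC, had 3 of 17 members at least 4-fold higher, none lower and 14 between, with a median of 0.65 inside the random range of -1.04 to 1.27. The 3 became 2 with median-of-ratios or TMM factors and 5 with the total without the 10 most abundant miRNAs. miR-20a-5p was 3.18-fold higher, miR-25-3p 1.56-fold higher and miR-92a-3p had a log2 ratio of -0.86.

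Of 11 miR-15 and miR-16 family members, 3 were at least 4-fold higher, 1 was at least 4-fold lower and 7 lay between, with a median of -1.0003. The 3 higher ones, miR-195-5p, miR-195-3p and miR-497-5p, were above 0 only in SHP77, at 228, 164 and 113 CPM, whereas miR-15b-5p was 5.01-fold lower and miR-16-5p was at 1640 CPM in H446 and 819.7 CPM in SHP77. The 1 lower member became 3 with median-of-ratios or TMM factors and 0 with the total without the 10 most abundant miRNAs. Of 11 miR-30 members, 4 were at least 4-fold lower, none was higher and 7 lay between. The 4 were both miR-30a arms, miR-30c-2-3p and miR-30c-5p, at 34888 CPM in H446 and 3866 CPM in SHP77; the list median of 0.21 turned to -0.16 with median-of-ratios factors and was -1.48 over the 8 members at 100 CPM or more. Of 11 miR-23-27-24 members, 1 was at least 4-fold lower and 10 lay between, with a median of -0.90. That member was miR-23a-3p, 11.8-fold lower, while miR-27b-3p was at 20981 and 22245 CPM. Of 8 miR-181 members, 4 were at least 4-fold higher, 1 was lower and 3 lay between, with a median of 1.89; it was -0.08 over the 5 members at 100 CPM or more. With median-of-ratios or TMM factors 3 were at least 4-fold higher, since miR-181d-5p had log2 ratios of 1.97 and 1.92. With the library totals miR-181d-5p was 5.06-fold higher and miR-181a-2-3p 5.68-fold lower. Of 6 HOX cluster miRNAs, 2 were at least 4-fold higher, 2 lower and 2 between, with a median of -0.97. With TMM factors 1 was higher and 3 were lower. miR-10a-5p, on chromosome 17 within HOXB3, was 6.87-fold higher, and miR-196a-5p was 6.49-fold lower. The medians of these 5 lists lay inside the ranges of their random lists.

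Of 23 miRNAs linked to drug response in lung cancer, 9 were at least 4-fold higher in SHP77, 4 at least 4-fold lower and 10 between. Their median log2 ratio was -0.26, inside the random range of -0.79 to 1.44, and it turned to 0.38 over members at 1 CPM or more and to 0.73 with the total without the 10 most abundant miRNAs. The 4 lower members were miR-155-5p, miR-221-3p, miR-221-5p and miR-222-3p, and miR-7-5p, miR-379-5p and miR-200b-3p were among the higher ones. Several of these are members of other lists as well. miR-34a-5p, a miRNA induced by p53, was 10.6-fold lower (95% interval 7.06 to 16.8), at 230 CPM in H446 and 21.7 CPM in SHP77, and miR-449c-5p was 6.79-fold higher at 5.55 and 37.7 CPM. miR-29a-3p was at 1845 and 1350 CPM, and miR-29b-3p at 18.1 and 188 CPM. No chromosome 19 cluster miRNA reached 10 CPM; 8 names were above 0 in H446, with a sum of 21.1 CPM, and none in SHP77, where they could not be detected below 8.48 CPM each. Of the 8 names 6 had the same 26 counts and may share reads; with each count taken once the sum was 6.34 CPM. The miR-302 with miR-371-373 clusters and the miR-506-514 cluster were listed at 0 in both libraries.

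**Figure D3:**
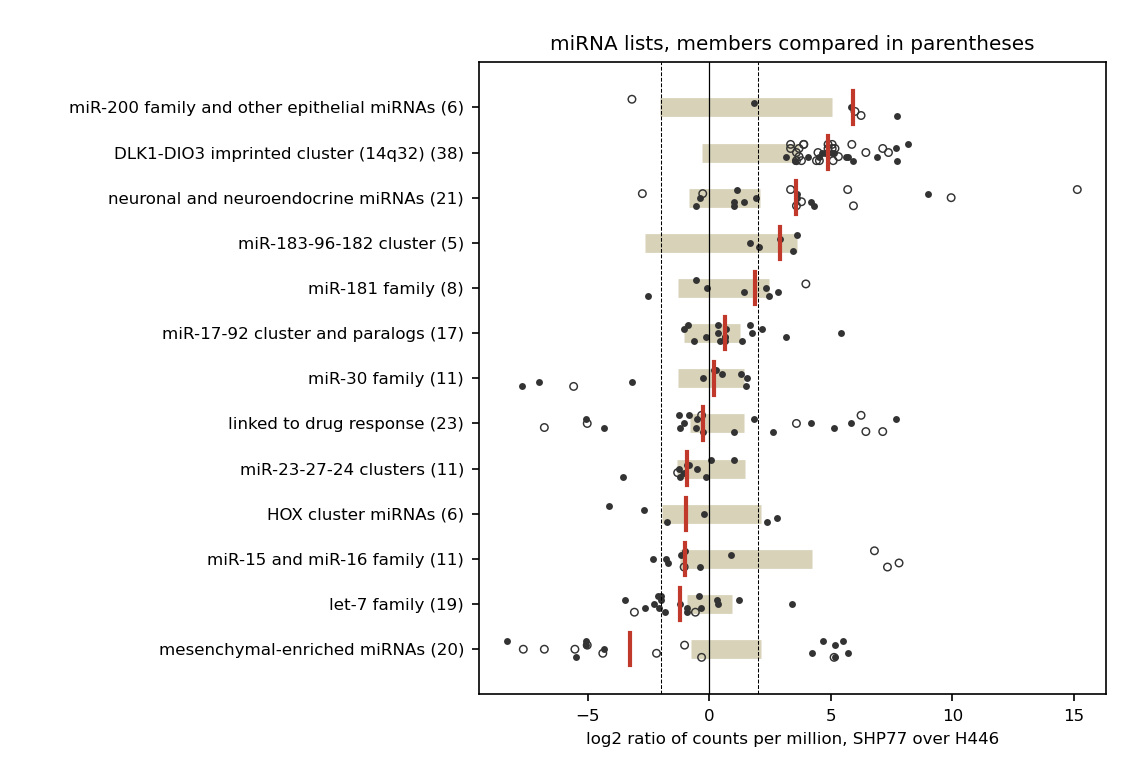
Log2 ratio of CPM, SHP77 over H446, of each list member compared (points; open where a library listed 0, so that the value is a bound), with the list median in red and the range of 95% of random lists of the same size in beige. Dashed lines mark 4-fold differences, and the DLK1-DIO3 cluster has all of its 38 members to the right of 4-fold.

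The listed markers of other cell types (blood cells, endothelium, muscle and liver) were low in both libraries. Their sum was 238 CPM in H446 (95% Poisson interval 228 to 248) and 555 CPM in SHP77 (95% interval 511 to 602). Most of it was the endothelial miR-126-3p, at 172 and 440 CPM, followed by the blood cell miRNA miR-486-5p, at 58.6 and 65.01 CPM. miR-451a, of red blood cells, was at 1.59 and 30.2 CPM and the liver miR-122-5p at 2.83 and 19.8 CPM. The muscle markers were listed at 0 in both libraries. They do not include miR-143-3p, abundant in smooth muscle, which was at 27.4 CPM in H446 and 706 CPM in SHP77.

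Ratios between the arms of a hairpin do not depend on library scaling. Of the 72 hairpins with all arms listed in both libraries, 14 differed by at least 4-fold in the ratio of 5p to 3p counts. A further 58 hairpins had an arm listed at 0, and 3 of them differed by at least 4-fold by a bound, which does not hold for miR-181b, as given below. In 26 the same arm was at 0 in both libraries, so no difference could be seen. Among the 72 hairpins, 70 had the same more abundant arm in both libraries, and the Spearman correlation of their arm ratios was 0.949. The 5p arm of miR-32 made up 55.8% of its counts in H446 and 91.8% in SHP77, a log2 difference of 3.14 (95% interval 2.63 to 3.66). The 5p share of miR-340 was 52.4% in H446 and 89.0% in SHP77, and that of miR-582 was 37.8% and 7.25%. The 3p names compared for miR-181b and miR-301a were listed at 0 in H446 and had 17 and 21 counts in SHP77. With these names the arm ratios differed by at least 4.52 and 3.34 on the log2 scale. For miR-181b this is not a bound on the arm ratio, because a second 3p name, miR-181b-2-3p, was above 0 in H446 and was left out. For miR-181a the 3p count likewise left out miR-181a-2-3p, at 5337 counts in H446 and 113 in SHP77. The 5p name of miR-181b pools hairpin genes on chromosomes 1 and 9, so its ratio is not that of a single hairpin; of the 72 hairpins, 4 likewise had a name that pools several hairpin genes.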

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

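No paired analysis was possible because each cell line has 1 library. Under every alternative tried, more of the differing miRNAs were higher than lower in SHP77. The 247 miRNAs differing at least 4-fold became 249 with median-of-ratios factors, 253 with TMM factors, 248 without the 10 most abundant miRNAs in the total and 252 with no minimum level. At 100 CPM or more, where fewer miRNAs were compared, 123 differed, of which 75 were higher and 48 lower. At least 2-fold lower were 132 miRNAs, and with 1 CPM added 110 were at least 4-fold lower, since a listed 0 then counts as 0. Alternatives chosen after seeing the data gave 132 among miRNAs above 0 in both libraries (92 higher, 40 lower), and 117 higher with H446 thinned to the SHP77 total. The miR-181 median reversed to -0.0844 at 100 CPM or more, where 5 members were compared. With the most abundant miRNA of each library left out, the next 10 held 58.3% of the remaining counts in H446 and 60.4% in SHP77. The markers of other cell types summed to 520 CPM in H446 and 1543 CPM in SHP77 without the 10 most abundant miRNAs in the total. The hairpins with a 4-fold difference in arm ratio were 13 at 200 counts or more and 19 with 1 count added to each arm, against 17 in total. The 17 include miR-181b, for which the bound does not hold. The number of named miRNAs differing at least 4-fold was 50, and from 50 to 52 under the alternatives. Single miRNAs near 4-fold, such as miR-182-5p, miR-181d-5p and miR-15b-5p, passed or missed that size by scaling. The ratios themselves depended on scaling. With median-of-ratios factors, 62 named ratios left their counting interval or had a changed bound, and 14 did not. With TMM factors these were 64 and 12, and without the 10 most abundant miRNAs in the total 61 and 15. miR-7-5p, at a log2 ratio of 4.21 (counting interval 4.19 to 4.22), went to 3.83, 3.79 and 4.55 in the same order. Of 13 list medians, 11, 11 and 13 left their counting interval. Depth limited SHP77 most, where 10 counts equal 9.42 CPM.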

Other observations

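The tests of carry-over between the libraries with their limits, and the miRNAs and neighbours named in this part, were chosen after the values had been seen, as was the use of draws and of TMM factors as the spread of the share of higher miRNAs. A first test of carry-over, of the median share needed against the limit from a miRNA at 0, was replaced after its result was seen, because the minimum of 10 counts largely fixed its outcome. Neighbouring miRNA genes often differed alike. miR-193b-3p and miR-365a-5p, neighbours on chromosome 16, had log2 ratios of -4.79 and -4.33, and miR-221-3p and miR-222-3p on chromosome X had -4.34 and -5.08. miR-143-3p and miR-145-5p on chromosome 5 had 4.69 and 5.73. miR-132-3p and miR-212-3p, neighbours on chromosome 17 and induced by neuronal activity, had 1.03 and 1.01. miR-301b-3p was at 2.72 CPM in H446 and 71.6 CPM in SHP77, while its neighbour miR-130b-5p on chromosome 22 was at 301 and 707 CPM. The more abundant arm of miR-18a switched, with the 5p arm at 23.8% of its counts in H446 and 67.5% in SHP77.

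Of the miRNAs differing at least 4-fold, 71.7% were higher in SHP77, and limits of 55% or less for a technical source and 65% or more against it were set before the tests. With H446 thinned to the SHP77 total the share was 62.7% (61.3 to 64.9% over 100 draws). Median-of-ratios factors gave 66.3% and TMM factors 64.4%, and thinning with median-of-ratios factors gave 67.0% (63.3 to 70.2%). None of these values came down to 55%, but each explanation had a value or a draw under 65%. Thinning took the number higher in SHP77 from 177 to 117 and left the number lower at 69 against 70. Unequal depth therefore added to the number called higher. With library totals the share was 71.7% before thinning and 62.7% after it. With median-of-ratios factors it was 66.3% before thinning and 67.0% after it. Those factors were computed anew on each thinned draw, so these shares differ in scaling as well as in depth. They cannot show how much of the share is due to depth alone. How far depth, scaling or both together make up the excess cannot be told apart from a difference between the lines, which was not tested.

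A hypothesis is that part of the differences is set per primary transcript, shared by the hairpins of a cluster. Across 114 pairs from 75 hairpins in 26 clusters, the median absolute log2 difference within a cluster was 1.32, against 3.21 in random pairings (95% between 2.38 and 3.96), and without the largest cluster it was 1.41 against 2.62 (1.85 to 3.36). This is in line with the hypothesis. Some neighbours still differed: miR-19a-3p had a log2 ratio of 5.43 and miR-92a-1-5p of -1.05, miR-23a-3p had -3.56 and miR-27a-3p -0.48, and let-7c-5p had -2.64 and miR-99a-5p -8.30. A GC bias as the source of such gaps stays open: the Spearman correlation of ratio with GC within clusters was -0.205 over 107 miRNAs (random range -0.228 to 0.214), between the limits of -0.4 and -0.2 set before, and GC of the hairpin is a proxy for the mature sequence. Removal of a GC trend left 104.5% of the miRNAs differing at least 4-fold (254 against 243), which argues against a GC trend as the whole source of that count.

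Many miRNAs abundant in a library had low counts in the other, as molecules carried over between libraries could give, which would bring all miRNAs at a single share. Of the 34 miRNAs above 0 in H446 that were at 100 CPM or more and at least 16-fold higher in SHP77, the 95% counting intervals of at most 11 (32.35%) held any single share, and of the 13 chosen alike in the other direction those of at most 5 (38.46%). The 0 of miR-375-3p in H446 allows at most 0.00278% of SHP77 molecules there, while miR-148a-3p and miR-7-5p, more abundant than it in SHP77, needed 0.570% and 5.42%, and the 0 of miR-224-5p in SHP77 allows at most 0.0748% of H446 molecules, while the 4 more abundant miRNAs needed from 0.317% (miR-99a-5p) to 2.98%. For miRNAs less abundant than these markers, a need above the limit follows from the minimum of 10 counts and was not used. These values argue against carry-over at a single share as the whole source of the low counts. The limits also cap the part that a single share could give to each miRNA. The need was 0.198% (miR-9-5p) or more among the 34 in H446, with a median of 2.25%. Among the 13 in SHP77 it was 0.317% or more, with a median of 2.96%. A part within these limits and low expression in these lines remain open.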
